A study of Arabidopsis thaliana with 12 samples.

How the data were processed

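Leaf RNA of 3 genotypes (Ws, Col, Col(gl)), each at 0 and 100 mM NaCl, was measured on Affymetrix arrays, 1 array per sample and 2 biological replicates per combination, 12 arrays in all. Per the labels, total RNA was used to make biotin-labelled cRNA, and the authors processed the scans with GCOS and RMA, whose versions and settings are not stated. The deposited values are log2 RMA signals, 1 per probe set and array, and were used without further normalization. The Col arrays also belong to another deposited series. Groups were taken from the sample labels.

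The table held 22810 probe sets, with 0 missing values. After 64 control probe sets were left out, 22746 were tested. Of these, 13513 were listed with 1 gene, 503 with several and 8730 with none, and 13436 of the 1-gene probe sets could be matched to a table of gene symbols. Genes are named only from 1-gene probe sets. Some well-known salt genes (RD29A, RD29B, P5CS1, NCED3, SOS1, NHX1, HKT1) and the genes GL1, FLC and AOP2, which the rule for naming genes includes, are not named in the table used here and have no value. RefSeq symbols are printed with the locus at first mention, or the locus alone where no symbol is given.

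Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit with 1 coefficient per group, eBayes; 6 residual degrees of freedom, prior degrees of freedom 3.45). Contrasts gave the salt response in each genotype, its average, the differences of responses between genotypes with a moderated F test, and the genotype differences at each salt level. P-values are two-sided and adjusted by Benjamini-Hochberg over all tested probe sets within each comparison, and a probe set was called at an adjusted p under 0.05. Errors are standard errors of the fitted log2 difference. On simulated data with known changes placed in the Ws arrays, the fit recovered 10% of changes of 0.5 log2 units, 84% of 1, 94% of 2 and 96% of 3, with 6 false calls. The simulated noise was independent, with 1 SD per probe set on all arrays. In the data the pooled replicate SD was 0.353 in salted Ws against 0.1445 in its controls, and some arrays deviated together. These shares therefore do not describe the real salt contrast of Ws. Overlaps of called probe sets were tested with Fisher's exact test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

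The gene lists, the comparisons, the rule for named genes and the alternatives were chosen before the data were examined, except where the text says otherwise. The rule names, for each comparison, up to 10 called 1-gene probe sets with the largest differences in each direction. It also names up to 4 called members of each list. For single salt responses and genotype differences, the groups compared may not overlap in those largest differences. For the averaged response all 3 responses must go in its direction. For differences of responses, the responses compared must go in opposite directions. Of 25 lists with 461 members, 66 members were measured under a name and 11 lists had at least 3. These were abscisic acid and dehydration response, antioxidant enzymes, nuclear photosynthesis genes, jasmonate, glucosinolate metabolism, flavonoid and anthocyanin synthesis, cell wall expansion, senescence, heat shock, trichome development and reference genes. Each list was tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the 11 lists within a comparison, on 1 probe set per gene; camera with an estimated correlation and fry were alternatives. Families of at least 5 genes sharing a symbol stem, and 69 plastid-encoded genes, were added after the data were seen and adjusted as a group of their own.

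Alternatives were the replicate number as a block, a filter on the lowest 25% of mean signal, quantile renormalization, an intensity trend with a robust prior, array weights, a fit of only the groups compared, an additive model, and leaving out each array in turn. Added after seeing the data were leaving out replicate 1 of Ws and Col at 100 mM together, a covariate for plastid-encoded signal, and a block with crossed replicate numbers. The array weights came out equal for both arrays of each group, so they weighted groups and could not discount a single array. Replicate numbers carry no stated pairing. Where 1 array of a group was left out, the remaining array was assumed to vary like the other groups.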

Results

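Gene expression was measured in leaves of Arabidopsis thaliana plants of 3 genotypes, given as Ws, Col and Col(gl). Ws and Col are the usual short names of the accessions Wassilewskija and Columbia. What sets Col(gl) apart from Col is not stated in the labels. Soil-grown plants received either no salt or NaCl raised in steps to 100 mM, and RNA was taken 20 days after sowing, 6 days after the start of the salt treatment. Each of the 6 combinations of genotype and salt was hybridised to 2 arrays, which the study describes as biological replicates, giving 12 arrays with 22746 probe sets tested on each. The number of arrays limits the precision of every value below. Array medians lay between 6.15 and 6.38 on the log2 scale, and lower quartiles between 4.19 and 4.42. Signals under or at that quartile are not shown to be above background, so differences from them are read as lower bounds, and differences between responses that both start there are not exact. By group means, among genes named in the text this concerns AT3G02480, PYK10, AT4G27654 and BHLH101 without salt, PYK10 and AT4G27654 in Col(gl) and BHLH101 in Ws also with salt, AT1G05340 without salt in Ws and Col, and BSMT1 without salt in Ws and Col(gl). It also concerns AT1G66100 and AT3G47250 in Ws, and COR27 in Ws and in Col without salt, and AOP3 lay close to the quartile.

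The arrays parted by genotype and by salt. The first principal component held 45.9% of the variance, ran from Ws without salt to Col(gl), and also moved the salted Ws and Col arrays towards Col(gl). The second held 25.9% and set the salted Ws and Col arrays apart from their controls, while the 4 Col(gl) arrays lay close together. Replicates correlated at 0.996 in Ws and Col without salt and in Col(gl) at both salt levels, at 0.984 in Col with salt and at 0.977 in Ws with salt. Replicate 1 of Ws and of Col with salt had low signal from plastid-encoded genes, with medians of 8.73 and 9.48 against 11.2 and 11.4 in the replicate 2 arrays of the same groups. On the same replicate 1 arrays the actin control probes differed most between the 3' and 5' ends of the transcript, by 3.70 and 3.68 log2 units, against at most 2.69 on the other 10 arrays. Plastid-encoded signal was also low on both arrays of Col(gl) without salt, at 10.34 and 10.35, against 11.56 and 11.58 with salt.

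**Figure D1:**
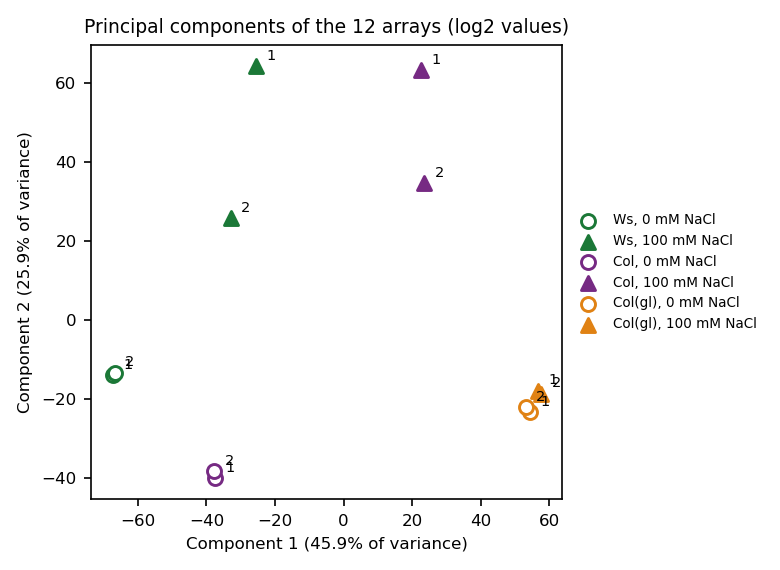
Each point is 1 array, placed by the first (45.9% of the variance) and second (25.9%) principal components of the log2 values, with open circles for 0 mM NaCl, filled triangles for 100 mM and the replicate number beside each point. The salted Ws and Col arrays lie above their controls, and the 4 Col(gl) arrays lie together.

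Salt in Ws raised dehydration genes and single genes of cell wall remodelling, while the cell wall expansion list went both ways. All 4 measured members of the fixed list of abscisic acid and dehydration response genes rose. LTI30 (AT3G50970), a dehydrin, rose by 2.66 ± 0.32 (log2, ± SE, 2 arrays per group, adjusted p = 0.00062) and COR47 (AT1G20440), another dehydrin, by 2.18 ± 0.28. The chloroplast protective proteins COR15B (AT2G42530) and COR15A (AT2G42540) rose by 1.5 ± 0.14 and 1.32 ± 0.18, the latter a call that ended with only the Ws arrays in the fit. AT3G02480, a gene of the late embryogenesis abundant type, rose by at least 7.15 ± 0.24 (adjusted p = 5.9e-07), from a signal of 3.98 that lay under the lower quartile of the arrays. XTH19 (AT4G30290), a xyloglucan-modifying enzyme, and EXLA1 (AT3G45970), an expansin-like protein, rose by 4.72 ± 0.29 and 4.48 ± 0.21. BSMT1 (AT3G11480), which makes methyl salicylate, rose by at least 4.67 ± 0.54.

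As a set, the dehydration list lay above the other genes in Ws (median 1.84, adjusted p = 8.9e-06, and adjusted p = 0.31 with an estimated correlation). All 4 members were also higher adjusted over the list alone. The senescence list had 1 of 3 members called, and 3 of 3 adjusted over the list alone, with a median of 1.83 (adjusted p = 0.01, and adjusted p = 0.42 with an estimated correlation). Its called member was WRKY53 (AT4G23810), a regulator of leaf senescence, which rose by 2.30 ± 0.20. STZ (AT1G27730), a zinc-finger repressor, rose by 3.13 ± 0.33. Of 4 trichome genes 3 fell and 1 rose, both over all probe sets and adjusted over the list alone, and the list as a set was not called (adjusted p = 0.23). Among them TRY (AT5G53200), a repressor of trichome fate, changed by -1.40 ± 0.16, and GIS (AT3G58070), a promoter of trichome formation, by -1.12 ± 0.29. GIS stopped being called in 6 of the alternative settings. The calls of SIM (AT5G04470), an inhibitor of mitosis in trichomes, at -0.49 ± 0.14, and of the sole riser, AT5G06700, at 0.67 ± 0.14, ended in 14 and 4. Of the cell wall expansion genes, 2 of 5 were higher and 2 lower, also adjusted over the list alone. The set was not called (adjusted p = 0.97), and its median (-0.05) and the direction of the test were negative while its mean (0.27) was positive. The expansin EXPA4 (AT2G39700) fell by 1.21 on the log2 scale (SE 0.11), and XTH33 (AT1G10550) rose by 2.40 ± 0.33, a call that ended with only the Ws arrays in the fit.

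PDF1.2 (AT5G44420), a defensin that marks the jasmonate and ethylene response, changed by -1.16 ± 0.15 in Ws. With 1 of 3 jasmonate genes higher and 1 lower on both counts, the jasmonate list as a set was not called (adjusted p = 0.69). The antioxidant list had 1 of 5 higher and 1 lower on both counts and was not called as a set (adjusted p = 0.97). CCS (AT1G12520), the copper chaperone of superoxide dismutase, rose by 0.90 ± 0.13, a call that ended with only the Ws arrays in the fit, and TAPX (AT1G77490), the thylakoid ascorbate peroxidase, changed by -0.80 ± 0.09. Of the glucosinolate genes 2 of 4 were lower on both counts (adjusted p = 0.23 for the set), and of the nuclear photosynthesis genes 1 of 8 was lower and 0 adjusted over the list alone (adjusted p = 0.23). On both counts 0 of 5 flavonoid (adjusted p = 0.97), 0 of 4 heat shock (adjusted p = 0.61) and 0 of 6 reference genes (adjusted p = 0.92) were called by limma. The flavonoid median (0.01) and mean (0.14) were positive while the test pointed down. The plastid-encoded genes, tested as a family added after the data were seen, had 12 of 69 members lower and a median of -1.21 (adjusted p = 2.8e-10, and adjusted p = 0.68 with an estimated correlation). The low plastid-encoded signal and the wide actin 3' to 5' difference of replicate 1 with salt stand beside that value, and beside the change of -2.01 ± 0.32 in rpl16, a plastid-encoded ribosomal protein gene.

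In total 3779 of 22746 probe sets were called in Ws, 2084 higher and 1695 lower, of which 785 and 257 changed at least 2-fold. After quantile renormalization the balance turned to 1864 higher and 2120 lower. The count was 1567 or 1874 without either array of Ws at 0 mM (replicate 1, replicate 2), 2488 without replicate 1 at 100 mM, 5902 without replicate 2 at 100 mM, and 865 with only the Ws arrays in the fit.

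Salt in Col raised the same 4 dehydration genes and lowered genes of anthocyanin synthesis. LTI30 rose by 4.74 ± 0.32 (log2, ± SE, 2 arrays per group, adjusted p = 8.6e-06), COR15B by 1.90 ± 0.14, COR47 by 1.07 ± 0.28 and COR15A by 0.68 ± 0.18; the calls of COR47 and COR15A ended in 4 and 3 of the alternative settings. AT3G02480 rose by at least 6.43 ± 0.24, AT1G05340 by at least 5.47 ± 0.38 and AT4G29780 by 5.14 ± 0.13. EXLA1 rose by 5.05 ± 0.21, STZ by 4.65 ± 0.33, and WRKY53 by 3.22 ± 0.20. PYK10 (AT3G09260), a beta-glucosidase of endoplasmic reticulum bodies, rose by at least 4.98 ± 0.89, with salted arrays far apart at 9.99 (replicate 1) and 7.73. In Ws, where it was not called, the salted arrays read 6.73 (replicate 1) and 3.61. PDF1.2 fell by 3.73 on the log2 scale (SE 0.15), to a mean of 7.14 from 10.9, below its level in Ws with salt, 9.33.

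Of the 5 flavonoid and anthocyanin genes measured, 4 fell in Col, also when adjusted over the list alone. UGT78D2 (AT5G17050), a flavonoid glucosyltransferase, changed by -1.75 ± 0.15 (adjusted p = 4.2e-05) and UF3GT (AT5G54060), an anthocyanin glycosyltransferase, by -1.61 ± 0.21. As a set the list had a median of -1.69 (adjusted p = 0.025, and adjusted p = 0.23 with an estimated correlation). Glucosinolate genes were lower in 3 of 4 cases, adjusted over the list alone as well, with a median of -0.66 (adjusted p = 0.041, and adjusted p = 0.23 with an estimated correlation), among them BCAT4 (AT3G19710), an enzyme of methionine chain elongation, at -0.82 ± 0.13. The dehydration list had a median of 1.48 (adjusted p = 0.001, and adjusted p = 0.23 with an estimated correlation), with 4 of 4 members higher adjusted over the list alone. The senescence list had 2 of 3 members higher on both counts and a median of 1.41 (adjusted p = 0.041, and adjusted p = 0.36 with an estimated correlation), a call lost after quantile renormalization (adjusted p = 0.069) and with the low-intensity filter (adjusted p = 0.095).

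Other lists in Col were not called as sets, though members of some passed the test. Of the jasmonate genes 1 of 3 was higher and 2 lower (adjusted p = 0.26), PDF1.2 and JMT (AT1G19640), which makes methyl jasmonate, at -1.70 ± 0.18. In the trichome list 2 of 4 genes were lower (adjusted p = 0.24), TRY at -2.10 ± 0.16 and GIS at -1.99 ± 0.29. Nuclear photosynthesis genes were lower in 3 of 8 cases, and in 4 adjusted over the list alone (median -0.28, adjusted p = 0.064). Antioxidant genes were higher in 1 of 5 cases and lower in 2, or in 4 adjusted over the list alone (adjusted p = 0.42), with CCS at 1.41 ± 0.13 and TAPX at -0.78 ± 0.09. Cell wall expansion genes were higher in 1 of 5 cases, or in 2 adjusted over the list alone, and lower in 2 (adjusted p = 0.77), with EXPA4 at -1.18 ± 0.11. Heat shock genes (0 of 4, adjusted p = 0.7) and reference genes (0 of 6, adjusted p = 0.77) were not called by limma, and the same 10 genes gave 0 calls adjusted over the list alone.

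In total 8529 probe sets were called in Col, 3733 higher and 4796 lower, of which 1681 and 928 changed at least 2-fold. The median over all tested probe sets was itself -0.13 in Col (-0.06 after quantile renormalization), against -0.03 in Ws and -0.02 in Col(gl), and changes in Col are read relative to it. Without replicate 1 of Col at 0 mM the count was 5263.

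**Figure D2:**
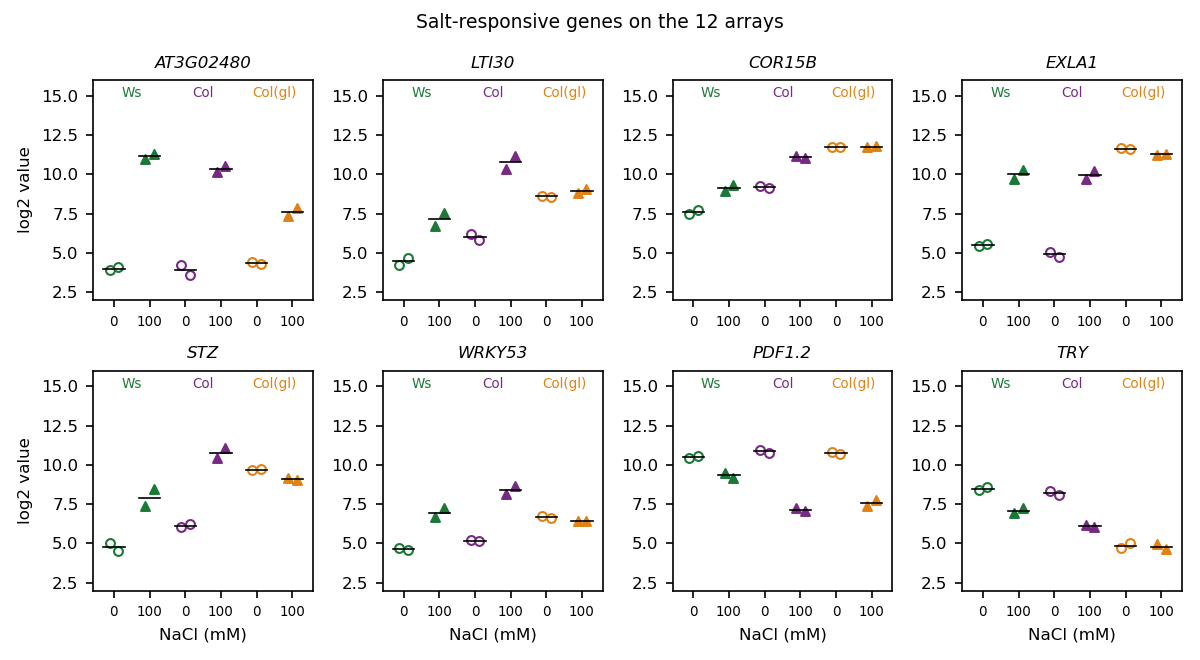
Log2 values of 8 genes on the 12 arrays at 0 and 100 mM NaCl in the 3 genotypes, with 1 point per array (open circles without salt, filled triangles with salt) and a line at the mean of each pair. AT3G02480 rose in all 3 genotypes and PDF1.2 fell in all 3, while LTI30, COR15B, EXLA1, STZ and WRKY53 rose in Ws and Col, and TRY fell there.

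Salt in Col(gl) was called for fewer probe sets than in Col, and for none of the 4 measured members of the dehydration list. Most members of that list, such as RD29B, RAB18 and NCED3, had no value. AT3G02480 rose by at least 3.26 ± 0.24 (log2, ± SE, 2 arrays per group, adjusted p = 0.00046), from a signal of 4.35, and AT5G05250 by 2.35 ± 0.15. XTH19 rose by 2.66 ± 0.29, a call that ended without any 1 of the 4 Col(gl) arrays. PDF1.2 fell by 3.18 on the log2 scale (SE 0.15, adjusted p = 6.6e-05), and AT1G04770 by 2.18 (SE 0.17). UGT74B1 (AT1G24100), a glucosyltransferase of the glucosinolate core pathway, changed by -1.16 ± 0.09.

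The glucosinolate list was the one set whose call held with an estimated correlation: 2 of 4 genes were lower, and 3 adjusted over the list alone, with a median of -0.57 (adjusted p = 6.6e-05, and adjusted p = 0.041 with an estimated correlation). Of the dehydration genes 0 of 4 were called by limma on either count, with a median of 0.01 (adjusted p = 0.95), LTI30 at 0.31 ± 0.32 and COR15B at 0.02 ± 0.14. Their Col(gl) means without salt were already 11.7 (COR15B), 12.3 (COR15A), 11.2 (COR47) and 8.62 (LTI30), against 11.1, 12.4, 10.8 and 10.8 in salted Col. A general lack of a dehydration response is therefore not shown. The nuclear photosynthesis list was called as a set with 0 of 8 members called, or 1 adjusted over the list alone, at a median of -0.20 (adjusted p = 0.011, and adjusted p = 0.39 with an estimated correlation). Antioxidant genes were lower in 1 of 5 cases, or lower in 3 and higher in 1 adjusted over the list alone (adjusted p = 0.06), and jasmonate genes in 1 of 3 on both counts (adjusted p = 0.067). On both counts 0 of 3 senescence (adjusted p = 0.98), 0 of 4 trichome (adjusted p = 0.95) and 0 of 5 flavonoid genes (adjusted p = 0.53) were called by limma. The senescence list had a median of 0.04 and a mean of 0.02 while its test pointed down. The plastid-encoded genes had 2 of 69 members higher and a median of 0.88 (adjusted p = 4.2e-10, and adjusted p = 0.84 with an estimated correlation), beside a plastid-encoded signal that was low in the Col(gl) controls.

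In total 339 probe sets were called in Col(gl), 179 higher and 160 lower, of which 55 and 62 changed at least 2-fold, and 3377 had an unadjusted p under 0.05. After quantile renormalization the balance turned to 162 higher and 185 lower. The order against Ws depended on the fit: with only the arrays of each genotype the count was 1338 in Col(gl) against 865 in Ws and 6111 in Col. With arrays weighted by their spread, equally within each group, it was 1915 against 2784 in Ws and 7555 in Col. In alternatives chosen after seeing the data it was 2398 with a covariate for plastid-encoded signal, against 3711 in Ws and 9268 in Col, 1987 with both plastid-low arrays left out, against 3984 in Ws and 8458 in Col, and 3027 with only the Col(gl) arrays in the fit and crossed replicate numbers as pairs, beside the 1338 of that fit without pairs. Leaving out 1 array gave 31 without either array of Col(gl) at 0 mM, and 28 and 33 without replicate 1 or 2 at 100 mM. It gave 167 without either array of Ws at 0 mM, 175 without either of Col at 0 mM and 690 without either of Ws at 100 mM.

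Responses in Ws and Col were called for many of the same genes, and those of Col(gl) for few of them. Of the probe sets called higher, 1544 were shared by Ws and Col against 342 expected if independent, and 1263 of those called lower against 357 (one-sided Fisher's exact test, log10 p of -861 and -536). The genotypes share 1 estimate of spread per probe set, so calls can coincide whatever their direction. Probe sets are also not independent, so the Fisher p-values here do not by themselves measure a shared response. Among 2892 called in both, 85 changed in opposite directions. Across probe sets, which are not independent replicates, the Ws and Col responses correlated at r = 0.731 with a slope of 0.532 for Ws on Col. Part of this can come from replicate 1 of both with salt, which deviated together (r = 0.659 across nuclear-gene probe sets) and share the low plastid-encoded signal and the wide actin difference, unlike any salted Col(gl) array. With replicate 2 alone of the salted arrays, a check made after seeing the results, r was 0.65 across nuclear-gene probe sets, against 0.737 with both. Col(gl) shared 81 higher and 74 lower probe sets with Col against 29.4 and 33.7 expected (log10 p of -19 and -12), and 60 and 39 with Ws against 16.4 and 11.9 (log10 p of -19 and -10.6). Yet 92 of 247 called in both Col(gl) and Col, and 89 of 188 called in both Ws and Col(gl), changed in opposite directions, and the correlations were 0.158 and 0.0794. In all 3 genotypes 52 probe sets rose and 37 fell.

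**Figure D3:**
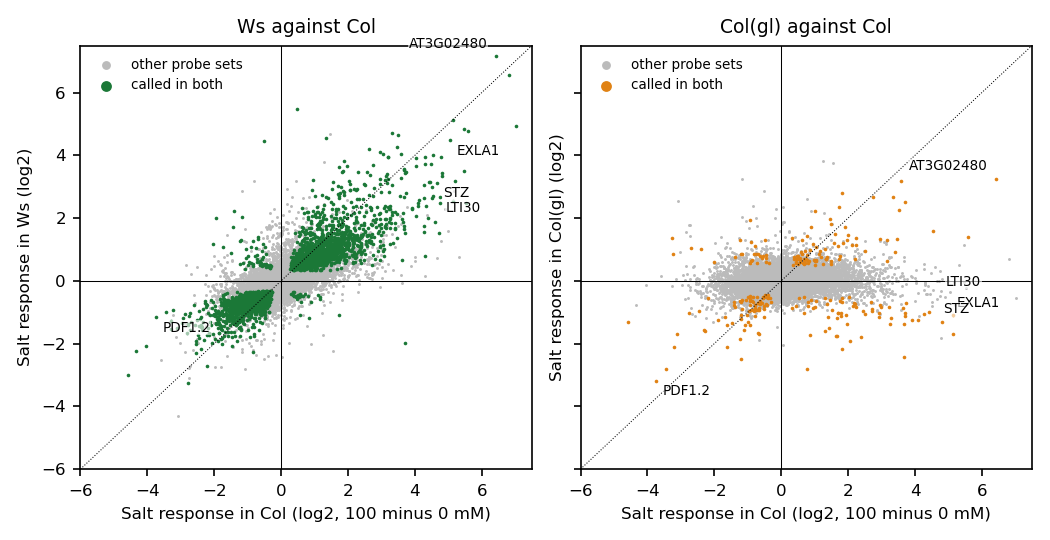
Salt responses of the 22746 probe sets (log2 difference, 100 minus 0 mM), with Col on the horizontal axis and Ws or Col(gl) on the vertical, coloured points called in both genotypes and the dotted line marking equal responses. The responses correlate at r = 0.731 for Ws and Col, and at r = 0.158 for Col(gl) and Col.

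Averaged over genotypes, AT3G02480 (5.62 ± 0.14, log2, ± SE, adjusted p = 7.2e-08), AT1G05340 (3.81 ± 0.22) and XTH19 (3.57 ± 0.17) rose and PDF1.2 fell, with a change of -2.69 ± 0.09. All 4 dehydration genes were called higher in this average, though 0 of 4 were in Col(gl) by itself, where their median was 0.01. In the average they were also higher adjusted over the list alone (median 1.1, adjusted p = 0.00022, and adjusted p = 0.26 with an estimated correlation). Nuclear photosynthesis genes were lower in 7 of 8 cases, also adjusted over the list alone, by a median of -0.22 (adjusted p = 0.017, and adjusted p = 0.31 with an estimated correlation). Glucosinolate genes were lower in 3 of 4 cases, or 4 adjusted over the list alone (adjusted p = 0.016, and adjusted p = 0.26 with an estimated correlation). Senescence genes were higher in 2 of 3 cases on both counts (adjusted p = 0.017, and adjusted p = 0.31 with an estimated correlation), a call lost with the low-intensity filter (adjusted p = 0.06). The test called 8612 probe sets, 3950 higher and 4662 lower, and 5172 in an additive model of genotype plus salt.

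Which genes responded differently between genotypes was tested directly on the difference of responses. AT1G47400, which encodes a small peptide of the IRON MAN family, changed by -1.97 ± 0.44 in Ws (not called without either array of Ws at 0 mM) but rose by 3.70 ± 0.44 in Col and 2.50 ± 0.44 in Col(gl), where the call ended in 8 of the alternative settings. Ws minus Col was -5.67 ± 0.62 (adjusted p = 0.0018). AT5G05250 behaved alike, with Ws minus Col at -2.80 ± 0.21 and Ws minus Col(gl) at -3.43 ± 0.21. On the other side Ws minus Col was 3.99 ± 0.47 for CHI (AT2G43570), annotated as a chitinase (adjusted p = 0.0025). It was 3.20 ± 0.43 for the expansin EXPA16 (AT3G55500) and 2.49 ± 0.30 for CML41 (AT3G50770), a calmodulin-like protein. For these genes both salted arrays lay above both controls in Ws and below them in Col. The naming rule required opposite directions for the largest differences of responses, here and below. A rise against a fall is therefore no result for genes named that way. In Col, EXPA16 read 7.85 and 7.8 without salt and 5.29 and 6.3 with salt, and CHI 9.37 and 9.46 against 8.2 and 9.03. PDF1.2 fell less in Ws, by a difference of 2.57 ± 0.22 from Col.

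Several genes that salt raised in Col had a lower response in Col(gl), and some that salt lowered in Col a higher one. The response was lower by -6.22 ± 0.18 for AT4G29780 (adjusted p = 2.4e-07), -5.41 ± 0.29 for EXLA1, -5.25 ± 0.34 for EXO (AT4G08950), a gene of cell expansion, -5.22 ± 0.47 for STZ, -4.43 ± 0.45 for LTI30 and -3.48 ± 0.29 for WRKY53. It was higher by 4.66 ± 0.25 for AT1G20070, which fell in Col (10.23 and 10.19 without salt, 6.66 and 7.2 with) and rose in Col(gl) (5.68 and 5.78, 7.04 and 7.19). The dehydration list had 2 of 4 members lower in Col(gl) than in Col, and 4 adjusted over the list alone (median -1.49, adjusted p = 0.00054, and adjusted p = 0.31 with an estimated correlation), and 4 of 4 members higher in Ws than in Col(gl) on both counts (median 1.85, adjusted p = 2.1e-05, and adjusted p = 0.3 with an estimated correlation). Senescence genes were higher in Ws than in Col(gl) in 1 of 3 cases on both counts (median 1.79, adjusted p = 0.029, and adjusted p = 0.3 with an estimated correlation), a call lost with the low-intensity filter (adjusted p = 0.054). The flavonoid list was called as lower in Col alone of the 3 genotypes by its set test (adjusted p = 0.025, and adjusted p = 0.23 with an estimated correlation). The differences themselves had 2 of 5 members called, or 4 adjusted over the list alone, for Ws minus Col (median 1.70, adjusted p = 0.00072, and adjusted p = 0.16 with an estimated correlation) and for Col(gl) minus Col (median 1.35, adjusted p = 0.03, and adjusted p = 0.31 with an estimated correlation). Without salt all 5 flavonoid genes were already lower in Ws and in Col(gl) than in Col. UF3GT, for instance, had means of 6.87 in Ws, 7.49 in Col(gl) and 10.5 in Col. The differences of response are not separated from this lower start. The response of TRY was -2.10 in Col and -0.06 in Col(gl), a difference of 2.04 ± 0.23, and its mean without salt was 4.86 in Col(gl) against 8.21 in Col.

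The F test of the interaction called 3587 probe sets. Pairwise, 1061 differed between Ws and Col (575 higher in Ws, 486 lower), 3947 between Col(gl) and Col (1995 and 1952) and 1415 between Ws and Col(gl) (830 and 585). Of these, differences of at least 2-fold were 326 higher and 326 lower, 812 and 1278, and 602 and 277. With both plastid-low arrays left out, an alternative chosen after seeing the data, these counts were 5603, 2525, 5468 and 2591. With a covariate for plastid-encoded signal, likewise added, they were 5721, 4155, 3709 and 2269. For Ws minus Col the count was 265 with only these groups in the fit. Its balance turned there (123 higher, 142 lower), with both plastid-low arrays left out (1194 and 1331) and without single arrays, such as replicate 1 of Ws at 0 mM (171 and 215). For Col(gl) minus Col it turned in several settings, such as the replicate block (2031 and 2053) and array weights (2560 and 2630), so neither direction is claimed.

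Leaving out 1 array moved each of these interaction counts. The F test called 2282 without replicate 1 of Ws at 0 mM, 5802 without replicate 2 of Ws at 100 mM, and 2022 and 2223 without replicate 1 or 2 of Col at 0 mM. It called 1741 and 1888 without replicate 1 or 2 of Col(gl) at 0 mM, and 1814 and 1979 without those at 100 mM. For Ws minus Col the counts were 386 and 421 without replicate 1 or 2 of Ws at 0 mM, 2169 without replicate 1 of Ws at 100 mM, and 395 and 488 without replicate 1 or 2 of Col at 0 mM. They were 683 without either array of Col(gl) at 0 mM and 664 without either at 100 mM. For Col(gl) minus Col they were 2320 and 2438 without replicate 1 or 2 of Col at 0 mM, 2087 and 2252 without those of Col(gl) at 0 mM, and 2172 and 2332 without those at 100 mM. For Ws minus Col(gl) they were 682 and 731 without replicate 1 or 2 of Ws at 0 mM, and 3551 without replicate 2 of Ws at 100 mM. They were 592 and 667 without replicate 1 or 2 of Col(gl) at 0 mM, and 634 and 732 without those at 100 mM.

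Without salt, Ws lacked high signal for several genes that were strong in both Col genotypes. Whether the probes match the sequences of all genotypes equally well was not tested, so values between genotypes are differences in signal. AT1G66100 and AT3G47250 read 4.02 and 3.77 in Ws, under the lower quartile of its arrays, so their differences from Col, -8.22 ± 0.14 (log2, ± SE, 2 arrays per group, adjusted p = 2.8e-09) and -6.34 ± 0.11, are lower bounds in size. ECS1 (AT1G31580) lay at -7.57 ± 0.36 and AT3G22240 at -6.63 ± 0.16. In the opposite direction AT2G15560 lay 4.73 ± 0.17 and AT2G35820 3.62 ± 0.22 higher in Ws. Probe sets that set 1 genotype apart from both others by more than 4 log2 units at both salt levels numbered 11 for Ws (1 higher, 10 lower), 0 for Col and 0 for Col(gl), and by more than 2 units 53, 0 and 35. All 5 flavonoid genes were lower in Ws than in Col, also adjusted over the list alone, led by DFR (AT5G42800), dihydroflavonol reductase, at -4.66 ± 0.62 and UF3GT at -3.64 ± 0.21. That set call held with an estimated correlation (median -3.08, adjusted p = 1.8e-07, and adjusted p = 0.032 with an estimated correlation). Of the dehydration genes 3 of 4 were lower in Ws, or 4 adjusted over the list alone (median -1.31, adjusted p = 0.00039, and adjusted p = 0.33 with an estimated correlation).

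Col(gl) without salt stood above Col for several genes that salt raised in Col and in Ws. EXLA1 was higher by 6.72 ± 0.21 (log2, ± SE, 2 arrays per group, adjusted p = 8.9e-08), EXO by 5.92 ± 0.24, STZ by 3.57 ± 0.33, LTI30 by 2.60 ± 0.32 and COR15B by 2.54 ± 0.14. COR27 (AT5G42900), a cold-regulated gene of the circadian system, was higher by 6.23 ± 0.20 and GI (AT1G22770), a clock component, by 1.54 ± 0.17. All 4 dehydration genes were higher, also adjusted over the list alone (median 1.96, adjusted p = 0.00025, and adjusted p = 0.2 with an estimated correlation). The trichome genes TRY and GIS were lower, at -3.34 ± 0.16 and -2.65 ± 0.29, and SIM was higher by 0.85 ± 0.14. The list went 2 up and 2 down on both counts and was not called as a set (adjusted p = 0.77). Flavonoid genes were lower in 5 of 5 cases on both counts (median -3.03, adjusted p = 4.5e-05, and adjusted p = 0.084 with an estimated correlation), with UGT78D2 at -3.25 ± 0.15. Glucosinolate genes were lower in 3 of 4 cases on both counts (median -0.73, adjusted p = 0.0095, and adjusted p = 0.12 with an estimated correlation), while AOP3 (AT4G03050), a side-chain enzyme of that pathway, was not called (-0.10 ± 0.14). Plastid-encoded signal was lower in these Col(gl) arrays than in Col, at 10.34 and 10.35 against 11.54 and 11.39. Against Ws without salt, the dehydration genes were lower in Ws than in Col(gl) in 4 of 4 cases on both counts (median -3.21, adjusted p = 5.2e-05, and adjusted p = 0.41 with an estimated correlation). The correlation of group means was 0.966 between Col(gl) without salt and Col with salt, and 0.952 between Col(gl) and Col without salt.

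At 0 mM 3594 probe sets differed between Ws and Col (1929 higher in Ws, 1665 lower), 5417 between Col(gl) and Col (2342 and 3075) and 7238 between Ws and Col(gl) (4355 and 2883). Differences of at least 2-fold were 367 higher and 634 lower, 1131 and 1083, and 1330 and 1513, so the balance was the opposite in each among large differences. Without replicate 2 of Ws it also turned for Ws against Col over all calls (804 higher, 988 lower), as it did without replicate 1 of Ws or replicate 2 of Col. For Ws against Col the count was 1643 and 1792 without replicate 1 or 2 of Ws, 1732 and 2089 without replicate 1 or 2 of Col, 5628 with arrays weighted by their spread and 5972 with only these 4 arrays in the fit. In alternatives chosen after seeing the data it was 6448 with both plastid-low arrays left out, 6419 with the plastid covariate and 7229 with only these 4 arrays in the fit and crossed replicate numbers as pairs. For Ws against Col(gl) that fit gave 11002, beside 9391 without pairs.

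**Figure D4:**
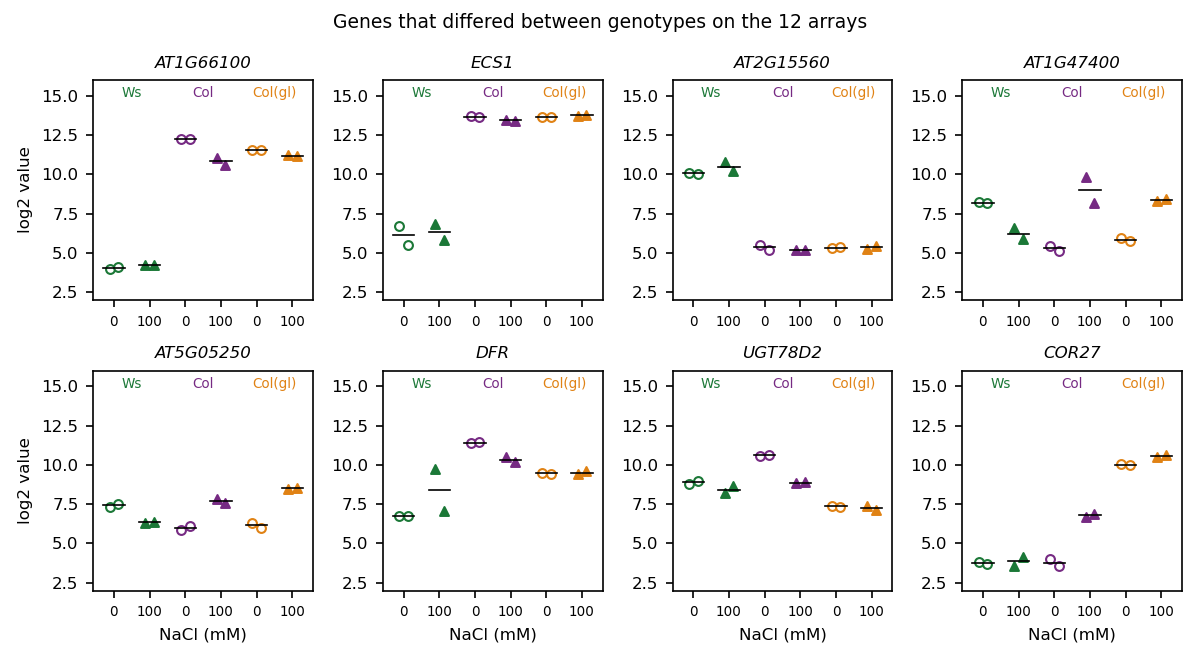
Log2 values of 8 genes on the 12 arrays at 0 and 100 mM NaCl in the 3 genotypes, with 1 point per array (open circles without salt, filled triangles with salt) and a line at the mean of each pair. AT1G66100 and ECS1 were low in Ws at both salt levels, AT1G47400 fell with salt in Ws and rose in Col and Col(gl), and COR27 was high in Col(gl) at both.

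With salt, Ws still differed most from Col in some of the genes that set it apart without salt, while several differences of Col(gl) from Col turned or widened. ECS1 was -7.07 ± 0.36 and AT1G66100 -6.58 ± 0.14 in Ws relative to Col (log2, ± SE, 2 arrays per group, adjusted p = 2.9e-06 and 1e-08), and AT2G15560 was 5.32 ± 0.17 higher. LTI30 and COR15B stayed lower in Ws than in Col, at -3.63 ± 0.32 and -1.99 ± 0.14, the call of LTI30 ending with only these arrays in the fit (adjusted p = 0.059). In Col(gl) relative to Col, COR27 was still 3.76 ± 0.20 higher, while PYK10 was -5.10 ± 0.89 (a lower bound in size, with Col(gl) at a mean of 3.76 with salt and salted Col arrays at 9.99 and 7.73), ORA47 (AT1G74930), a transcription factor of the jasmonate response, -4.78 ± 0.47, AT4G29780 -3.88 ± 0.13, STZ -1.65 ± 0.33 and LTI30 -1.84 ± 0.32. STZ and LTI30 had been higher in Col(gl) without salt.

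Flavonoid genes were lower than in Col in 3 of 5 cases in Ws, or 5 adjusted over the list alone (median -1.76, adjusted p = 6.1e-05, and adjusted p = 0.09 with an estimated correlation), and in 4 of 5 in Col(gl) on both counts (median -1.62, adjusted p = 0.0014, and adjusted p = 0.11 with an estimated correlation). Dehydration genes were lower in Ws than in Col in 2 of 4 cases, or 3 adjusted over the list alone (median -1.21, adjusted p = 0.0006, and adjusted p = 0.3 with an estimated correlation), and antioxidant genes were higher in 4 of 5 on both counts (median 0.42, adjusted p = 0.0053, and adjusted p = 0.3 with an estimated correlation). Glucosinolate genes were lower in Col(gl) than in Col in 2 of 4 cases, or 3 adjusted over the list alone (median -0.62, adjusted p = 0.011, and adjusted p = 0.11 with an estimated correlation). Between Ws and Col(gl), dehydration genes were lower in Ws in 2 of 4 cases on both counts (median -1.09, adjusted p = 0.031, and adjusted p = 0.38 with an estimated correlation) and glucosinolate genes higher in 3 of 4 on both counts (median 0.98, adjusted p = 0.031, and adjusted p = 0.27 with an estimated correlation). Each of these calls was lost with the low-intensity filter (adjusted p = 0.074), and that of the dehydration genes also with both plastid-low arrays left out, an added alternative (adjusted p = 0.095).

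At 100 mM 2896 probe sets differed between Ws and Col (1513 higher in Ws, 1383 lower), 5528 between Col(gl) and Col (2494 and 3034) and 7003 between Ws and Col(gl) (4254 and 2749). Differences of at least 2-fold were 336 higher and 699 lower, 704 and 983, and 1338 and 1278, the first opposite to the balance of all calls. For Ws against Col that balance also turned after quantile renormalization (1395 and 1424). The first count was 282 with only these 4 arrays in the fit, 1431 with arrays weighted by their spread (566 higher, 865 lower) and 5502 with the plastid covariate added after seeing the data. With only their own arrays in the fit, Col(gl) against Col gave 3597 and Ws against Col(gl) 4193. Quantile renormalization turned the balance of Col(gl) against Col (2795 higher, 2649 lower). Leaving out replicate 1 of Col at 100 mM gave 3165 for Col(gl) against Col, leaving out replicate 1 or 2 of Col(gl) gave 2772 and 3112, and Ws against Col(gl) was 4656 without replicate 1 of Col(gl).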

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

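Of the tests below, the share of salt genes raised in Col(gl) controls, the exchange of labels, the comparison of replicate spreads, the actin control signal and the sets from split controls were chosen only after the result was seen. The differences listed here were picked out because the test of the difference between genotypes passed; groups of 2 arrays allow no test for single stray arrays.

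By the F test the salt response differed between genotypes for 3587 probe sets, and pairwise for 1061 (Ws minus Col), 3947 (Col(gl) minus Col) and 1415 (Ws minus Col(gl)). Of 47 salt genes named here or in the results, 42 passed the F test, with adjusted p from 7.2e-07 to 0.034 in limma. Many were named for large differences of responses, so this share does not describe salt genes in general. Over all tested probe sets the F test called 15.8%. The pair of genotypes with the lowest unadjusted p is given for each of the 42. For Ws minus Col the differences (log2) were -5.67 for AT1G47400, -1.39 for PYE, 3.99 for CHI, 3.35 for AT5G58570, 3.20 for EXPA16, 2.57 for PDF1.2, 2.49 for CML41, 1.75 for UF3GT and 0.96 for BCAT4. Positive differences of Col(gl) minus Col were 4.66 for AT1G20070, 3.58 for AT2G15020, 2.04 for TRY, 1.92 for GIS, 1.90 for JMT and 1.63 for UGT78D2. Negative ones were -6.22 for AT4G29780, -5.41 for EXLA1, -5.25 for EXO, -5.22 for STZ, -4.75 for ATPMEPCRB, -4.68 for AT4G27654, -4.43 for LTI30, -4.34 for AT1G05340, -4.22 for AT3G15450, -4.0 for AT1G04770, -3.48 for WRKY53, -2.45 for GRX480, -1.88 for COR15B, -1.08 for CCS and -1.04 for GI. Ws minus Col(gl) was 4.05 for BSMT1, 3.89 for AT3G02480, 3.77 for XTH18, 2.53 for XTH33, 2.22 for COR47, 2.05 for XTH19, 1.33 for COR15A and 0.75 for UGT74B1, and -4.24 for rpl16, -3.43 for AT5G05250, -3.13 for AT1G11700 and -1.07 for EXPA4. The signals of BSMT1 and AT3G02480 without salt lay at or under the lower quartile of the arrays in both genotypes, as did those of AT4G27654 in Col and Col(gl), so these 3 differences are not exact.

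Col(gl) without salt differed from Col along the salt response of the other genotypes. An exchange of the salt labels within Col(gl) is argued against: over 2807 probe sets called in the same direction in Ws and Col, the Col(gl) response in that direction had a median of 0.11 (quartiles -0.07 and 0.30; Ws 0.76, Col 1.00), where an exchange needs a negative value. That the plants labelled 0 mM had received salt stays open, since a share of 0.705 of the strongly responsive probe sets (86 of 122, with 0 the opposite way) was already shifted, between the bounds set for either answer. These probe sets were chosen partly by the Col control arrays that also enter the shift, which can raise this share. Single genes went both ways. Without salt AT3G02480 had a mean of 4.35 in Col(gl) against 3.9 in Col and 10.3 in salted Col. The same means of PDF1.2 were 10.8, 10.9 and 7.14. Both genes were also called with salt in Col(gl), so they do not stand for the salt genes as a set. EXLA1 read 11.65 and 11.6 in Col(gl) without salt, against 9.72 and 10.19 in salted Col. The COR15B means were 11.7 in Col(gl) without salt and 11.1 in salted Col. The deviation of replicate 1 of Ws with salt stays open as a part of the pattern, as the correlation across 13444 nuclear-gene probe sets with replicate 2 alone was 0.40, against 0.443 with both and 0.409 with replicate 1, at the bound set in advance. A genetic difference of Col(gl), and an unrecorded difference in time or handling at harvest, cannot be separated by this design and were not tested.

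The salt response of Col(gl) was small in size, with 117 probe sets called and changed at least 2-fold against 1042 in Ws and 2609 in Col. A wider spread of its arrays could limit the number of calls but not the size of the differences. As a limit on calls it is argued against by their pooled replicate SDs, the larger of which was 0.144, below 0.353 in Ws and 0.297 in Col with salt. The main fit, however, shares its spread with these wider groups, so the count called in Col(gl) depends on them. A baseline already at the salt level stays open. Over the 1282 probe sets within 0.5 log2 units of Col without salt the Col(gl) response was 0.14, a share of 0.221 of the Ws response (0.65) and under the 0.25 set in advance. Of these probe sets 74.3% were themselves shifted in the salt direction, with a median shift of 0.17 over the set. In sets added after seeing this, the share was 0.277 within 0.1 and 0.275 where no such shift was seen. There the same control arrays entered both the choice and the response. With probe sets chosen by 1 replicate of the controls and the response taken from the other, the share was 0.217 and 0.219 within 0.5, 0.244 and 0.246 where no shift in the salt direction was seen, but 0.252 and 0.26 within 0.1, on both sides of the bound. It cannot be told apart from a weaker response of this genotype, and less salt reaching these plants was not tested.

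Replicate 1 of Ws and replicate 1 of Col with salt deviated together, with r = 0.659 between their deviations across nuclear-gene probe sets, which are not independent replicates. Degraded RNA or less complete labelling is a candidate explanation, since the actin 3' minus 5' signal of the lower array exceeded the highest of the other 10 by 0.99, though on the GAPDH control the lower of these arrays (1.00) lay under the highest other (1.05). A stronger salt response of these plants stays open, with a correlation of 0.216 between the deviation in Ws and the response of Col from its replicate 2, and -0.12 the other way round. Less chloroplast-rich tissue stays open: nuclear photosynthesis genes moved by -0.15 (Ws) and -0.10 (Col) while the median change per plastid-encoded gene was -1.40 and -1.39, short of the fall of 1.5 in the bound set in advance. By the array medians of plastid-encoded signal (8.73 against 11.2, and 9.48 against 11.4) that bound is passed, which would count against this explanation, so the answer depends on the summary.

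The count of probe sets with a salt effect was compared with other splits of the 12 arrays into 6 and 6, in a model of genotype plus split. Of 100 splits drawn from 462, 2 including the real one called as many as the real split (5172). This comparison cannot exclude a random grouping of the samples. Most splits part the replicates of some group, which correlated at 0.977 or higher, and such splits could call few probe sets whatever the source. The highest of the other splits called 5545: it put all Ws arrays and the salted Col arrays against the rest, which, with genotype in the model, is the salt contrast of Col alone and so a structure of the samples. The next highest called 22, and the median was 0.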

How the results depend on the processing

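The alternatives with both plastid-low arrays left out, the plastid covariate and the crossed pairing were chosen after seeing the data. No called named gene turned in the settings run for genes, and no list call in the settings run for lists, which did not include single arrays left out, the plastid covariate, separate fits or crossed pairs. The balance of higher and lower calls turned in some settings for several comparisons. The 14 counts stayed within 1.5 times their value with the replicate block (3840 for salt in Ws, 8650 in Col, 270 in Col(gl)), the low-intensity filter, quantile renormalization and the intensity trend with a robust prior. Causes of the moves below were not tested. A fit of only the groups compared has fewer arrays for the spread, which does not account for counts that rose. It also takes the spread from those groups alone. Pooled replicate SDs were 0.353 in salted Ws and 0.297 in salted Col, against 0.137 to 0.149 in the other groups. Of the counts below, those that rose in that fit involved no salted Ws or Col array, and those that fell did.

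With only the groups compared in the fit, the counts were 865 for salt in Ws, 1338 for salt in Col(gl), 265 for the difference of Ws and Col, 5972 for Ws against Col at 0 mM, and, at 100 mM, 282 for Ws against Col, 3597 for Col(gl) against Col and 4193 for Ws against Col(gl). Array weights gave 1915 for salt in Col(gl), 5628 for Ws against Col at 0 mM and 1431 at 100 mM, where the share called higher in Ws went from 52.2% to 39.6%. The additive model gave 5172 for the averaged response. With the plastid-low arrays left out, the counts were 1987 (salt in Col(gl)), 2525 and 2591 (differences of Ws from Col and from Col(gl)), 6448 (Ws against Col at 0 mM) and 5603 (F test). The plastid covariate gave 2398, 4155, 2269, 6419 and 5721 for the same 5 results and 5502 for Ws against Col at 100 mM. With only the groups compared in the fit and the replicate numbers crossed as pairs, the counts were 3027 for salt in Col(gl) (1338 in that fit without pairs), 7229 for Ws against Col (5972) and 11002 for Ws against Col(gl) at 0 mM (9391), and the numbers carry no stated pairing.

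Leaving out 1 array gave ranges of 1567 to 5902 for salt in Ws, 5263 to 9622 in Col, 28 to 690 in Col(gl) and 6787 to 9834 averaged; 386 to 2169, 2087 to 5375 and 592 to 3551 for the differences Ws minus Col, Col(gl) minus Col and Ws minus Col(gl); 1741 to 5802 for the F test. Between genotypes (same order) they were 1643 to 4553, 3716 to 6298 and 5150 to 8102 at 0 mM, and 2189 to 3685, 2772 to 6816 and 4656 to 7979 at 100 mM.

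Of 554 results for named genes, 3 lost their call with the replicate block, 8 with the intensity trend, 13 after quantile renormalization and 13 to 69 without 1 array. With only the groups compared, 69 lost it and 427 kept it. Of 143 list results, 28 lost their call with an estimated correlation, 0 with the replicate block, 5 of 130 with the low-intensity filter, 1 after quantile renormalization and 1 with the plastid-low arrays left out (dehydration genes, Ws against Col(gl) at 100 mM), while fry, which tests the list alone, called 50 more. Recovery of simulated changes of 0.5 log2 units was 10%, with equal and independent noise on all arrays, so a missing call does not show that a small change was absent.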

Other observations

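The symbol families in this part and the plastid-encoded genes were tested only after the results were seen, and no family call held with an estimated correlation (0 of 6 in Ws, 0 of 2 in Col, 0 of 2 in Col(gl)). In Ws 4 of 8 autophagy genes (ATG) rose with salt (median 0.32, adjusted p = 0.0081 by camera of limma, and adjusted p = 0.32 with an estimated correlation), as did 4 of 9 xyloglucan-modifying genes (XTH; median 0.61, adjusted p = 0.0097, and adjusted p = 0.32 with an estimated correlation) and 4 of 14 bZIP transcription factor genes (median 0.28, adjusted p = 0.028, and adjusted p = 0.32 with an estimated correlation). Calmodulin-like genes (CML) went 4 up and 1 down of 7 (median 1.02, adjusted p = 0.028, and adjusted p = 0.32 with an estimated correlation). Cytochrome P450 genes (CYP) were lower in 7 of 26 cases in Ws (median -0.18, adjusted p = 0.049, and adjusted p = 0.34 with an estimated correlation), and in Col in 11 with 1 higher (median -0.33, adjusted p = 0.035, and adjusted p = 0.58 with an estimated correlation). Of 5 tubulin genes (TUB) 4 rose in Col (median 0.85, adjusted p = 0.029, and adjusted p = 0.58 with an estimated correlation), and Col(gl) minus Col had 4 of 5 lower (median -0.97, adjusted p = 0.0021, and adjusted p = 0.61 with an estimated correlation).

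The iron homeostasis list had 2 measured members and was too small to test as a set. PYE (AT3G47640), a regulator of the iron-deficiency response, rose by 1.23 ± 0.20 in Col (log2, ± SE, adjusted p = 0.0015 in limma) and was not called in Ws (-0.16 ± 0.20) or Col(gl) (0.54 ± 0.20). BHLH101 (AT5G04150), whose signal without salt lay under the lower quartile of the arrays, rose by 0.72 ± 0.21 in Col, a call that ended in 5 of the alternative settings, and was not called in Ws (-0.09 ± 0.21) or Col(gl) (0.98 ± 0.21). The difference between Ws and Col was called for PYE (-1.39 ± 0.29, adjusted p = 0.028), though not in 9 of the alternative settings, and no difference between genotypes was called for BHLH101 (adjusted p = 0.17, 0.6 and 0.069). No explanation was tested.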
